A study of Coilia nasus with 12 samples.

How the data were processed

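The series holds RNA sequencing libraries from liver of field-caught *Coilia nasus*, 6 from feeding and 6 from fasting fish, sequenced on an Illumina HiSeq instrument. Per the labels' protocols, livers were frozen on dry ice, RNA was extracted with Trizol, and 1 µg of total RNA per library entered an mRNA library kit. The labels give the feeding status, the tissue and a library number, and no sex, age, maturity, date or batch.

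The deposited table holds 1 column of TPM values per library for 23159 assembled genes, with their length, symbol and protein description, made by the authors. The header names no unit: TPM was inferred from the values, because no column sums to over 1e+06, the column totals lie close together while the medians differ, and the values carry decimals. Every gene in the table reaches at least 8.01 TPM in some library, so weakly expressed genes were left out before deposit, and 84.6% to 94.3% of each library's TPM is in the table. The gene identifiers have the form that the Trinity assembler gives. The submitters' processing notes name edgeR without a version or role. The assembler, aligner, quantification tool and annotation databases are not given in the sources used here. No genome was used, so genes have no coordinates. Symbols and descriptions are those of the deposited table, taken from matches to other species, and 7681 genes have a symbol and 9751 a description. TPM holds no read counts, so no interval for counting error can be given. A value of 0 means only that a gene is listed at 0, which holds for 15.6% of the values.

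The design fixed before the data were examined provided for a count model, and for limma on log values if the table held normalised values. Since the values were TPM, the limma test was used. Genes with a mean of at least 1 TPM over the 12 libraries were kept (21806 genes), and log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with the group as the single factor and no block, a mean-variance trend and robust moderation. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. Fold changes are fasting minus feeding on the log2(TPM + 1) scale, which understates the change of genes with low values. Means and SDs are of TPM over 6 libraries.

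Gene lists were fixed before the data were examined: 32 pathway lists with 897 symbols, and 12 lists of cell type markers. Symbols were matched without regard to case, with endings for fish gene copies allowed. Genes with an invertebrate match or a match to the bat genus *Rhinolophus* were left out. Of the pathway symbols, 609 matched a gene and 604 a tested gene. Where several assembled genes carried a name, the one with the highest mean stood for it. The match rests on the symbol alone: LCP1 in the macrophage list is described as cathepsin L1-like, F2 in the coagulation list as a zinc finger protein, and mogat2-a in the intestine list as 2-acylglycerol O-acyltransferase 1-like. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 against all other tested genes, with adjustment over the pathway lists and, separately, over the cell type lists. Camera with a correlation estimated in each list, and fry, were run as alternatives. Members were also counted past the threshold over all genes and adjusted over the list alone. Of the 15 pathway lists that passed with the preset correlation, the egg protein list was the 1 that passed with an estimated correlation, and the intestine list passed with both. The estimates for these lists were 0.0209 and -0.0872, close to or below the preset 0.01, so the alternative was hardly stricter for them.

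The rule for named genes, also fixed beforehand, took up to 6 genes per direction with the largest fold change, among genes past the threshold with an informative annotation, a mean of at least 1 TPM in the higher group and group ranges that did not overlap, 1 per gene name. It also took up to 3 members with the smallest p of each list that passed, and allowed the most abundant member of the other lists.

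Genes were counted as ribosomal-RNA-like (79 genes) by the names ART2 and TAR1, genes of yeast that lie within ribosomal DNA, or by a match to the nematode genus *Trichinella*, which the most abundant gene named ART2 also had. Most of their TPM lies in a few genes described as hypothetical proteins. That they are ribosomal RNA was inferred from the annotation after the data were seen and was not tested, as the table holds no sequences. Genes with a match to other nematodes (1128), a plant source of the Swiss-Prot match (482) or a match to the bat genus *Rhinolophus* (256) were counted apart. Library measures were compared with two-sided exact permutation tests over the 924 splits of the 12 libraries, on log2 values.

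The limma and camera steps were tested on simulated data made from the mean and within-group spread of each of the 21806 genes, with noise independent between genes, in 5 rounds with 200 changed genes each, drawn from genes with a mean of at least 5 TPM. The test recovered 2.67% of genes with an absolute log2 fold change of 1, 46.0% of those with 2 and 82.2% of those with 3, and 16 of 452 calls (3.54%) were false. A respiratory chain list shifted by -1 was found, and 1 of the 31 other lists was called as well. In the data this list had an estimated correlation of 0.796 between its genes, so these rates of false calls need not hold there.

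Alternatives fixed beforehand were median ratio scaling, quantile normalization, no filter and a stricter filter, pseudocounts of 0.1 and 0.01, a fit without robust moderation, a minimum fold change, annotated genes alone, an exact rank-sum test, the library number as a block, and leaving out each library in turn. Added after the data were seen were leaving out fasting 1 and 2, alone or with median ratio scaling, setting aside the 10 most abundant genes or genes of other organisms, and the log2 vitellogenin total as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.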

Results

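Liver RNA of *Coilia nasus*, the estuarine tapertail anchovy, was sequenced from field-caught fish that were feeding or fasting, with 6 libraries in each group. Expression was given as TPM, an abundance relative to the whole library, for 23159 de novo assembled genes, of which 9840 carried a symbol or a protein description. The libraries held between 846027 and 943437 TPM in these genes, and between 18724 and 20219 genes stood above 0 per library. TPM keeps no read counts, so the sequencing depth of each library is unknown. The labels number the libraries within each group and do not say whether each came from a separate fish, so p-values measure the spread between these libraries. Genes taken as ribosomal-RNA-like from their annotation, a few of which held most of this TPM, took 36.0% of TPM in fasting 1 and 42.4% in fasting 2, against 0.892% to 9.29% in the other 10 libraries. The median TPM was 2.53 in fasting 1, 2.19 in fasting 2 and 3.93 to 8.23 elsewhere.

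**Figure D1:**
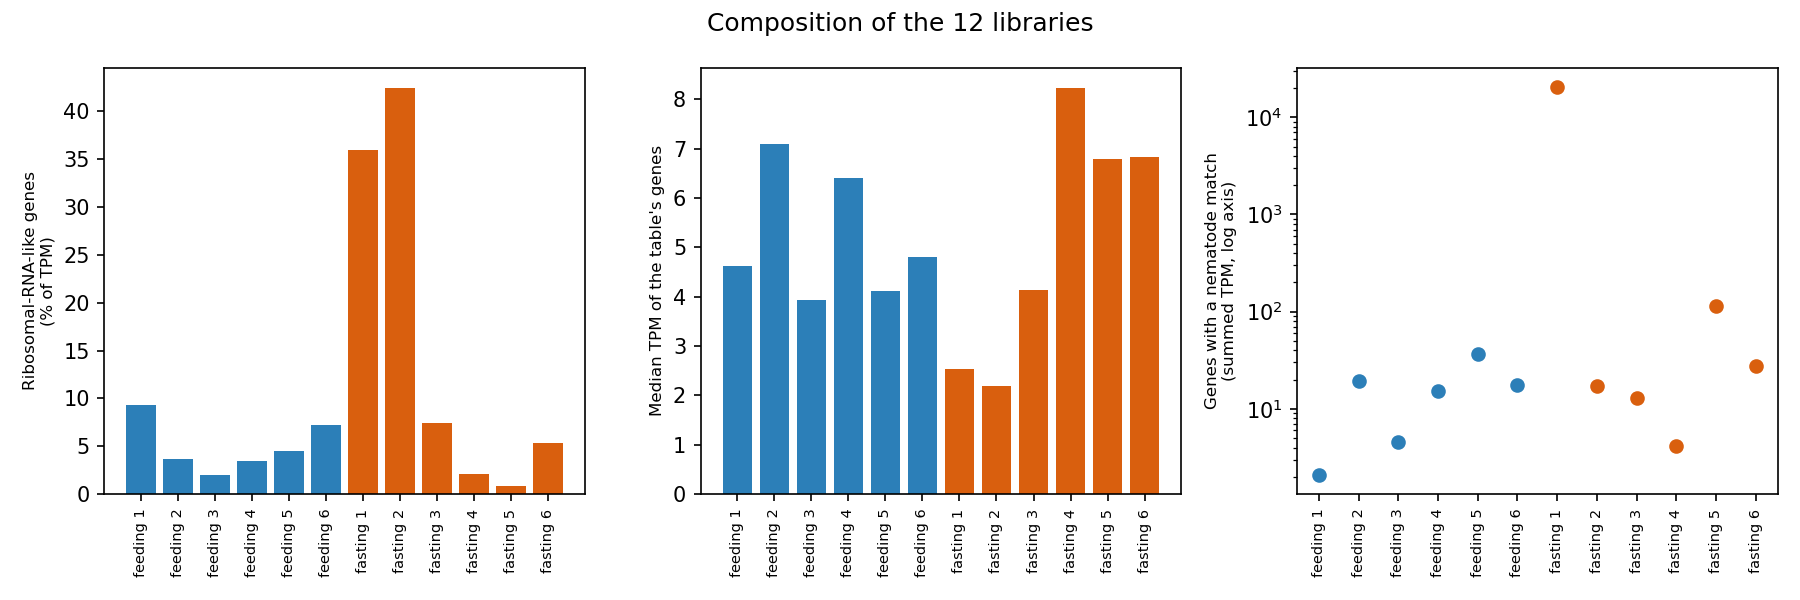
Composition of the 12 libraries. Bars give the percent of TPM in ribosomal-RNA-like genes (left) and the median TPM of the table's genes (middle), and points give the summed TPM of genes with a nematode match on a log axis (right), with feeding in blue and fasting in orange. Fasting 1 and fasting 2 stand apart in the first 2 panels with 36.0% and 42.4%, and fasting 1 in the third with 20544 TPM.

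The comparison asked how liver transcript levels of fasting fish differed from those of feeding fish. Egg protein genes, which a liver under estrogen transcribes for the eggs of a maturing female, fell as a list in fasting fish. The median log2 fold change was -2.36 over 8 tested members, with a much larger fall in vtg1, ZP3 and ZP4 than in the others. FABP2, a fatty acid carrier best known from the intestine, fell from 894 ± 700 TPM in feeding to 44.4 ± 65.3 TPM in fasting fish (SD, n = 6 each). ANXA6, a calcium-dependent membrane-binding protein, fell from 30.8 ± 13.8 to 3.20 ± 1.78 TPM. Lists for making fatty acids and cholesterol, oxidising fuel, breaking down amino acids and making and folding proteins also fell, with medians between -0.49 and -1.13, although with an estimated correlation between their genes none of these passed. Across single genes, 25 of 21806 were lower in fasting and 0 were higher, and under median ratio scaling or quantile normalization 0 passed in either direction.

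Of the 25 genes that fell, 14 had an annotation. By the rule for named genes, which asked for group ranges that did not overlap, 6 of them were singled out. Each therefore lay lower in all 6 fasting libraries than in any feeding library. Over all tested genes, 0.431% had group ranges apart in either direction, where chance gives 0.216%. FABP2 (TRINITY_DN39960_c0_g9) had a log2 fold change of -5.03 (SE 0.81, adjusted p = 0.0137). Fkbp11 (TRINITY_DN37676_c2_g5), a prolyl isomerase of the secretory pathway, fell from 104 ± 165 to 4.32 ± 4.04 TPM (log2 -3.54, adjusted p = 0.0258), with 439 TPM in feeding 1 alone. DOCK7 (TRINITY_DN41032_c0_g1), which activates small Rac-type GTPases, fell from 67.2 ± 61.0 to 5.84 ± 5.64 TPM (log2 -3.26, adjusted p = 0.00806). ANXA6 (TRINITY_DN45241_c0_g3) had a log2 fold change of -2.90 (SE 0.44) and the smallest adjusted p of the annotated genes, 0.000581. Aqp12 (TRINITY_DN37150_c2_g8), an aquaporin known in mammals from the acinar cells of the pancreas, fell from 30.7 ± 31.3 to 3.23 ± 2.25 TPM (log2 -2.64, adjusted p = 0.00872). CTBS (TRINITY_DN43934_c2_g2), a lysosomal glycosidase that takes apart the sugar chains of glycoproteins, fell from 96.2 ± 39.0 to 21.8 ± 16.1 TPM (log2 -2.39, adjusted p = 0.0444).

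**Figure D2:**
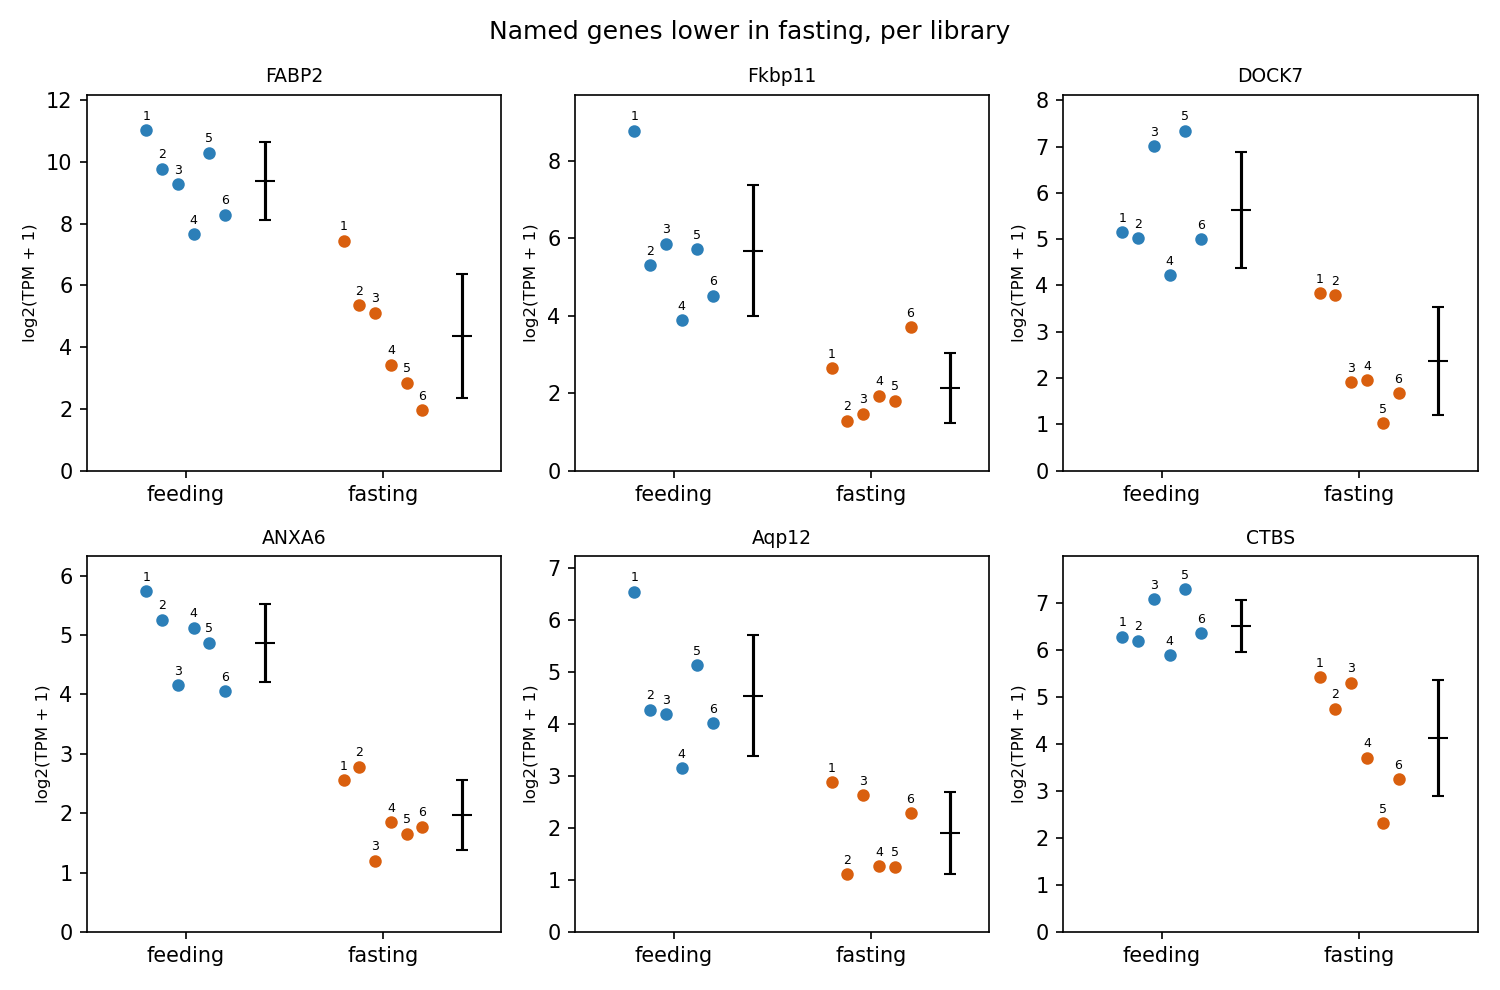
TPM of 6 named genes that fell in fasting, as log2(TPM + 1), with 1 point per library numbered by replicate, feeding in blue and fasting in orange, and the mean ± SD of each group in black. In each panel all 6 fasting libraries lie below all 6 feeding libraries, which the rule for choosing these genes required. ANXA6 had a log2 fold change of -2.90.

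The other 8 annotated genes that fell were outside that rule and were chosen after their values were seen. They included another assembled gene named fabp2 (log2 -2.76, adjusted p = 0.00117) and another named Ctbs (log2 -2.64, adjusted p = 0.0155). Assembled genes that share a name can share reads, so their separate levels are uncertain. The gene named calub, described as reticulocalbin-3, a calcium-binding protein of the endoplasmic reticulum, fell from 378 ± 217 to 42.0 ± 40.8 TPM (adjusted p = 0.00972). The gene lmf2, a lipase maturation factor, fell from 50.8 ± 48.6 to 6.78 ± 2.91 TPM (adjusted p = 0.0298), and Hdlbp, described as vigilin, from 121 ± 102 to 16.6 ± 6.94 TPM (adjusted p = 0.0486). CASP3, an executioner caspase, fell from 8.76 ± 3.33 to 1.16 ± 0.87 TPM (adjusted p = 0.0378). The last pair was described as uncharacterised.

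ANXA6 and the second fabp2 gene stayed past the threshold whichever of the 12 libraries was left out, but not under median ratio scaling (adjusted p = 0.246 and 0.430, log2 -2.61 and -2.43). FABP2 lost its call without feeding 5, fasting 2 or fasting 4 (highest adjusted p = 0.0823) and DOCK7 without fasting 4 (0.0647). Aqp12 lost its call without feeding 5 or fasting 4 (highest adjusted p = 0.0647), and Fkbp11 without feeding 5, fasting 2, fasting 4 or fasting 5 (0.141). CTBS lost its call without feeding 1, 3 or 5 or fasting 4, 5 or 6 (highest adjusted p = 0.210). Of the genes outside the rule, calub lost its call without feeding 5, fasting 2 or fasting 4 (highest adjusted p = 0.0754), lmf2 without feeding 1 or 5 or fasting 2 or 4 (0.120) and Ctbs without feeding 1 or 5 or fasting 4 or 5 (0.103). CASP3 lost its call without feeding 1, 2 or 5 or fasting 2, 4, 5 or 6, and Hdlbp without any of these or fasting 1 (highest adjusted p = 0.259 each). The calls of Fkbp11, lmf2, Hdlbp and Ctbs also ended without fasting 1 and 2 together, at adjusted p = 0.171, 0.128, 0.171 and 0.0622.

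Within the list of estrogen response and egg proteins, all 8 tested members had a negative fold change. The camera test passed with the preset correlation (adjusted p = 2.58e-09) and with an estimated one (adjusted p = 0.00399). The estimate for this list was 0.0209, close to the preset 0.01, so the second test nearly repeats the first. For the other pathway lists that passed, the estimates ran from 0.262 to 0.847. The fall was uneven: ZP4, vtg1 and ZP3 had log2 fold changes of -6.61, -6.56 and -6.31, against a list mean of -3.23 and median of -2.36. The median therefore describes no typical member. Without fasting 1 and 2 the median was -2.89 (adjusted p = 3.88e-10). Both of these libraries held a larger vitellogenin share than fasting 4, 5 and 6, so leaving them out deepens the fall. The call ended with the log2 vitellogenin total, built from genes of the list itself, as a covariate (median -1.15, adjusted p = 0.367), and the median was -0.62 with the 10 most abundant genes, vitellogenin genes among them, set aside, where the list still passed. No member passed over all genes, and 3 passed when adjusted over the list alone (list-adjusted p below). The egg envelope gene ZP3 averaged 6563 ± 4542 TPM in feeding and 477 ± 830 TPM in fasting fish (list-adjusted p = 0.0158). ZP4, another egg envelope gene, averaged 4420 ± 3710 and 329 ± 658 TPM (list-adjusted p = 0.0158). The most abundant gene named vtg1, for the yolk precursor vitellogenin, averaged 39872 ± 32675 and 4091 ± 5534 TPM (list-adjusted p = 0.0403). The estrogen receptor esr1 averaged 201 ± 118 and 65.3 ± 86.4 TPM and did not pass (list-adjusted p = 0.0555).

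All 11 assembled genes named vtg1 had a negative fold change, and together they took 9.10% ± 6.15 of TPM in feeding and 0.956% ± 1.23 in fasting libraries (SD, n = 6 each). The difference had a p of 0.00866 in a two-sided exact permutation test on log2 shares and of 0.0390 adjusted over 6 library measures, a test chosen after the values were seen. The share ran from 1.20% to 17.2% in the feeding libraries. It was 2.88% in fasting 1, 0.808% in fasting 2 and 2.04% in fasting 3, and 0.00466%, 0.000163% and 0.00669% in fasting 4, 5 and 6. The esr1 gene gave 219, 97.6 and 74.4 TPM in fasting 1, 2 and 3, and 0.32, 0.22 and 0.39 TPM in fasting 4, 5 and 6.

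**Figure D3:**
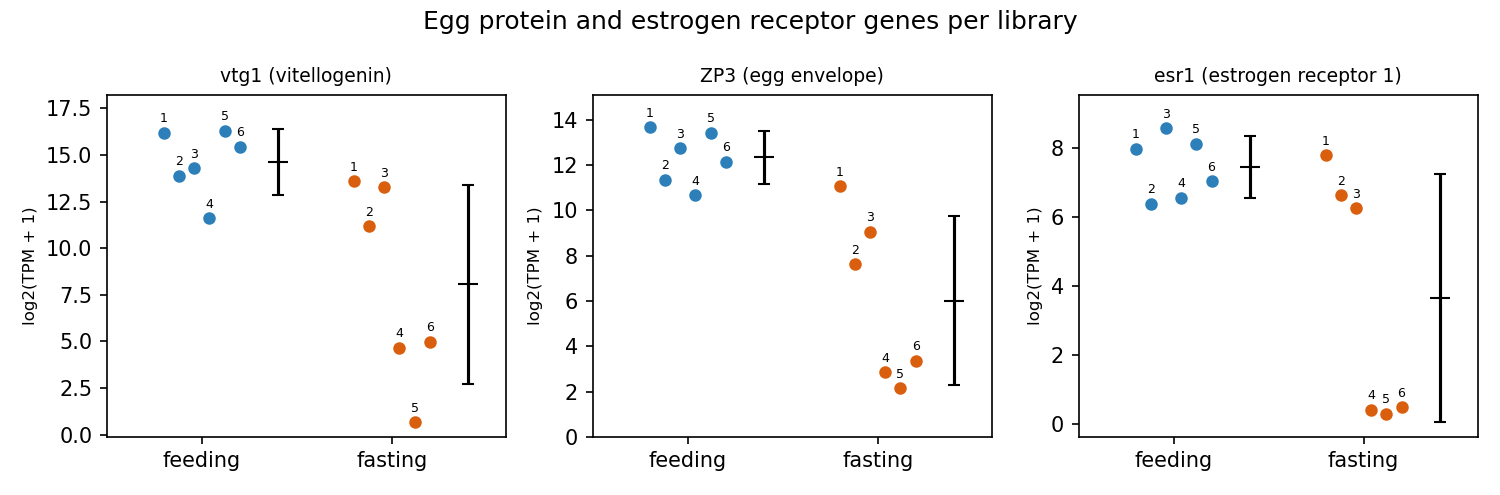
Egg protein and estrogen receptor genes per library, as log2(TPM + 1), with points numbered by replicate, feeding in blue, fasting in orange, and the mean ± SD of each group in black. The vtg1 points of fasting 4, 5 and 6 (24.2, 0.59 and 30.6 TPM) lie far below those of the other 9 libraries, the lowest of which holds 2343 TPM.

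The fatty acid synthesis list fell with a median log2 fold change of -1.06 over 12 members, 10 of them negative (adjusted p = 3.08e-06, and adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 3 members passed. FASN, the enzyme that builds palmitate, averaged 113 ± 133 TPM in feeding and 8.50 ± 1.49 TPM in fasting fish, with non-overlapping groups (log2 -2.73, list-adjusted p = 0.000883, over all genes 0.0594). ELOVL2, which elongates very long chain fatty acids, averaged 14.0 ± 13.8 and 3.29 ± 4.41 TPM (list-adjusted p = 0.0191). The desaturase gene fads2 averaged 34.0 ± 35.2 and 4.43 ± 3.85 TPM (list-adjusted p = 0.0191). The pentose phosphate list, a source of NADPH, fell with a median of -1.0, and 9 of its 10 members were negative (adjusted p = 1.58e-05, and adjusted p = 0.578 with an estimated correlation). Its members PGD (60.7 ± 70.5 and 7.99 ± 4.36 TPM) and TKT (68.6 ± 60.0 and 13.6 ± 6.07 TPM) passed when adjusted over the list alone (list-adjusted p = 0.00794 each). Without fasting 1 and 2 the medians of these 2 lists were -0.85 and -0.60. Leaving out these libraries also moved the median of all tested genes, from -0.13 to 0.23. With median ratio scaling as well, the medians of the 2 lists were -1.07 and -0.78.

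All 23 members of the cholesterol list had a negative fold change, and the list fell with a median of -1.02 (adjusted p = 3.23e-06, and adjusted p = 0.578 with an estimated correlation). The median was -0.60 without feeding 1 and -0.66 without fasting 1 and 2, the latter -0.87 with median ratio scaling as well. None passed when adjusted over the list alone. Acat2 averaged 21.3 ± 18.2 TPM in feeding and 4.13 ± 7.67 TPM in fasting fish, with 19.7 TPM in fasting 6. Triglyceride storage and lipolysis fell with a median of -0.54 over 14 members (adjusted p = 0.00814, and adjusted p = 0.578 with an estimated correlation). The 3 members that passed over the list alone were mogat2-a (73.1 ± 50.6 and 16.2 ± 6.79 TPM), DGAT2 (129 ± 48.9 and 38.6 ± 5.44 TPM) and LIPC (753 ± 317 and 257 ± 251 TPM), and mogat2-a and DGAT2 add acyl chains to glycerides. The list's median was -0.33 without fasting 1 and -0.01 without fasting 1 and 2 (adjusted p = 0.0216), the latter -0.17 with median ratio scaling as well. Fatty acid oxidation fell with a median of -0.49 over 27 members (adjusted p = 0.0205, and adjusted p = 0.742 with an estimated correlation). CPT1A, which admits fatty acids to the mitochondrion, averaged 26.7 ± 8.49 and 7.90 ± 6.11 TPM and was its 1 member past the threshold over the list alone (list-adjusted p = 0.00656). That list's call ended without feeding 6 (adjusted p = 0.0918), without fasting 1 (0.0744) and without fasting 1 and 2 (0.125, median -0.02), and its median was -0.29 without fasting 2. It also ended with a mean of at least 5 TPM (adjusted p = 0.111), with annotated genes alone (0.125) and with all assembled genes of a member (0.116, median -0.31). Without fasting 1 and 2 and with median ratio scaling the list passed (median -0.25, adjusted p = 0.0466).

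**Figure D4:**
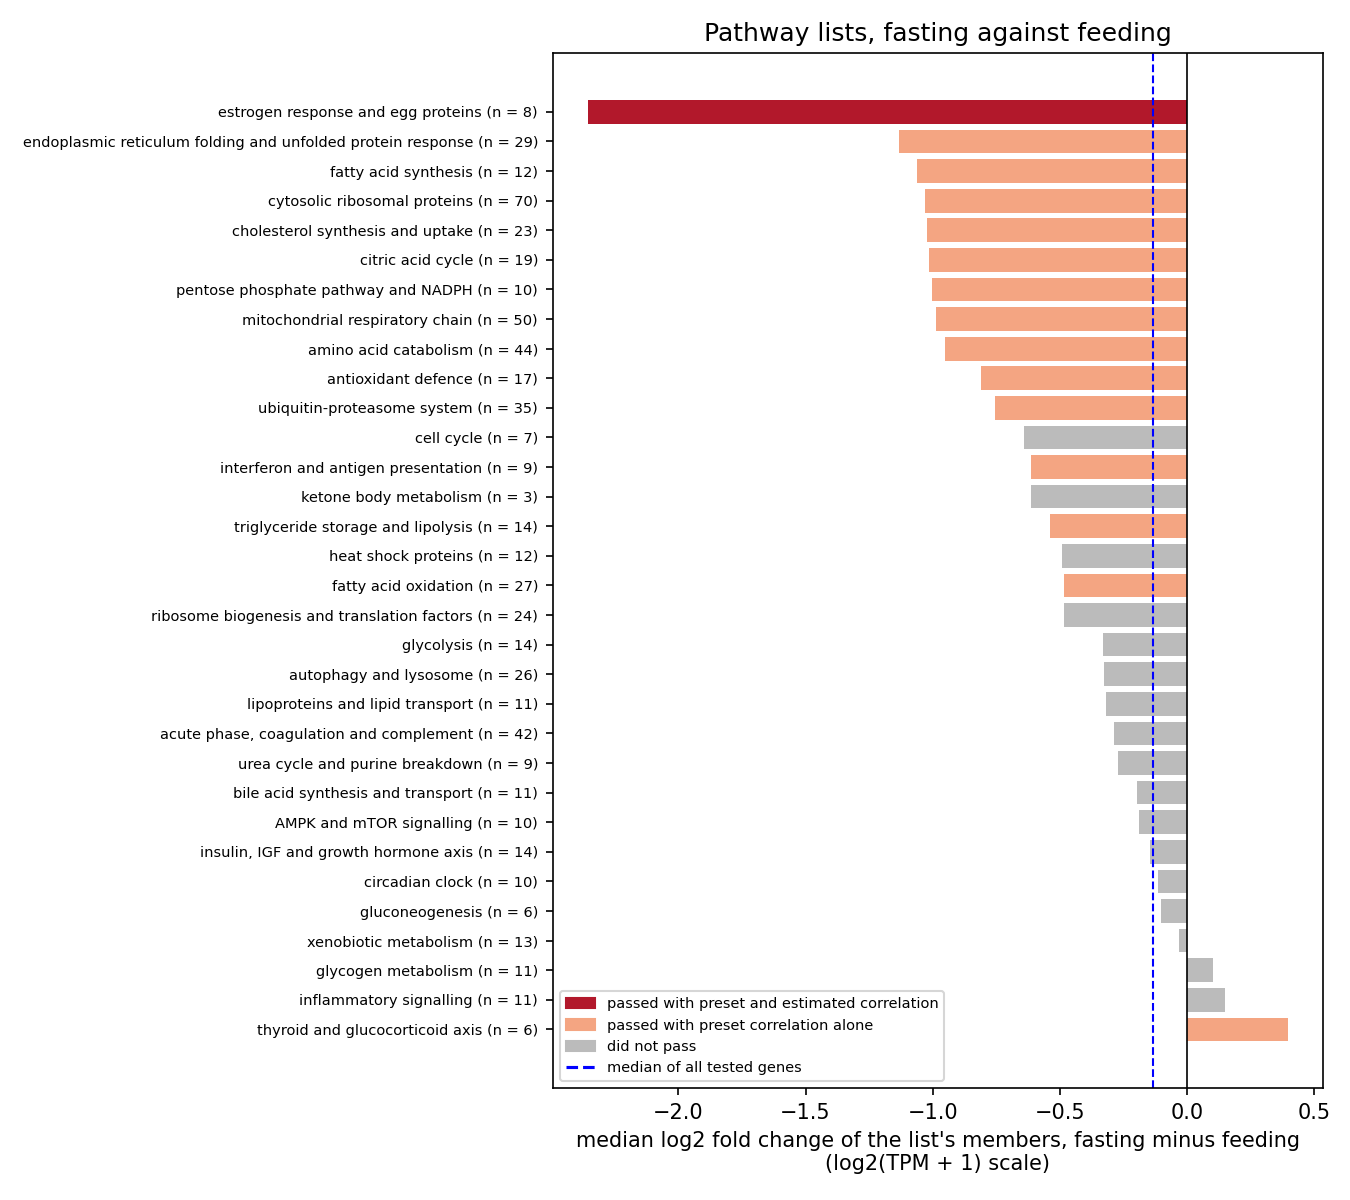
Median log2 fold change of the tested members of the 32 pathway lists, fasting minus feeding, on the log2(TPM + 1) scale. The dark bar passed with the preset and with an estimated correlation, pale bars with the preset alone, and grey bars did not pass. The dashed line marks the median of all tested genes, -0.13. The medians run from -2.36 for egg proteins to 0.40 for the thyroid and glucocorticoid axis.

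All 50 tested members of the respiratory chain list had a negative fold change, and it fell with a median of -0.98 (adjusted p = 1.65e-19, and adjusted p = 0.578 with an estimated correlation). The citric acid cycle fell with a median of -1.01 over 19 members (adjusted p = 2.32e-06, and 0.578 with an estimated correlation), of which the succinyl-CoA ligase genes SUCLG2 (44.4 ± 30.4 and 14.2 ± 8.27 TPM) and SUCLG1 (72.6 ± 43.5 and 22.0 ± 11.3 TPM) passed over the list alone (list-adjusted p = 0.0367 each). Amino acid catabolism fell with a median of -0.95 over 44 members (adjusted p = 6.34e-10, and 0.578 with an estimated correlation), and OAT (16.7 ± 7.13 and 3.95 ± 1.76 TPM) and SHMT1 (190 ± 98.7 and 57.3 ± 32.6 TPM) passed over the list alone (list-adjusted p = 0.0116 and 0.0464). The medians of these 3 lists were -0.44, -0.34 and -0.32 without fasting 1 and 2. With median ratio scaling as well, they were -0.67, -0.57 and -0.53. Mitochondrially encoded genes took 3.43% ± 1.05 of TPM in feeding and 2.23% ± 0.49 in fasting libraries (n = 6 each, two-sided exact permutation p = 0.0130, adjusted over the same 6 measures 0.0390). Without fasting 1 and 2 their share in fasting was 2.40% ± 0.46 (exact p = 0.0810), and outside the 10 most abundant genes the shares were 5.03% ± 2.27 and 3.92% ± 1.02 (exact p = 0.305).

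Cytosolic ribosomal proteins fell with a median of -1.03, and 67 of 70 members were negative (adjusted p = 3.75e-16, and adjusted p = 0.578 with an estimated correlation). RPL23A averaged 718 ± 342 TPM in feeding and 262 ± 142 TPM in fasting fish, and neither it nor any other member passed over the list alone. The endoplasmic reticulum list, which covers protein folding and the unfolded protein response, fell with a median of -1.13 over 29 members (adjusted p = 6.08e-10, and 0.578 with an estimated correlation). Its member SSR3, a subunit of the translocon-associated complex, averaged 173 ± 133 and 30.5 ± 18.4 TPM (list-adjusted p = 0.0268). The ubiquitin-proteasome list fell with a median of -0.76, and 34 of 35 members were negative (adjusted p = 2.20e-08, and 0.578 with an estimated correlation). Antioxidant defence fell with a median of -0.81 over 17 members (adjusted p = 0.000260, and 0.578 with an estimated correlation), and none of its members passed over all genes or over the list alone. The ribosomal median was -0.66 without fasting 2 and that of the endoplasmic reticulum list -0.72 without feeding 1. Without fasting 1 and 2 the medians of these 4 lists were -0.44, -0.70, -0.25 and -0.33, in that order, and the call of antioxidant defence ended (adjusted p = 0.0995, and 0.0506 with median ratio scaling as well). With that scaling as well, the 4 medians were -0.66, -0.86, -0.46 and -0.53.

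Interferon and antigen presentation fell with a median of -0.61 over 9 members (adjusted p = 0.0194, and adjusted p = 0.578 with an estimated correlation). Its 1 member past the threshold over the list alone was psmb9-a, an immunoproteasome subunit, with 25.9 ± 28.6 TPM in feeding and 5.02 ± 1.77 TPM in fasting fish (list-adjusted p = 0.0158). The call ended without feeding 2, which held 81.4 TPM of psmb9-a (adjusted p = 0.184, median -0.27), without fasting 6 (0.0537) and with annotated genes alone (0.0676), and the median was -0.38 without fasting 1 and -0.24 without fasting 1 and 2. With median ratio scaling as well, the last was -0.41. The thyroid and glucocorticoid list was the 1 list that rose, with a median of 0.40 and 6 of 6 members positive (adjusted p = 0.0374, and adjusted p = 0.578 with an estimated correlation). None of its members passed alone. The clock gene Per1 averaged 2.90 ± 2.12 TPM in feeding and 5.81 ± 4.17 TPM in fasting fish, and TSC22D3, which glucocorticoids induce in mammals, 7.46 ± 4.51 and 12.7 ± 8.01 TPM. The call ended without feeding 3 (adjusted p = 0.202, median 0.10), feeding 4 (0.0597), fasting 3 (0.0765), fasting 5 (0.119, median 0.16) or fasting 6 (0.0855, median 0.26), and with a pseudocount of 0.01 (0.0502). The median was 0.60 without feeding 2, 0.69 without fasting 1, 0.75 without fasting 2 and 0.26 without fasting 4. Without fasting 1 and 2 the median was 1.15 (adjusted p = 0.00114), and 0.96 with median ratio scaling as well.

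The other 17 pathway lists did not pass. Adjusted p was 0.0503 for the cell cycle, 0.0536 for heat shock proteins, 0.0763 for glycolysis, 0.0796 for ribosome biogenesis and translation factors, 0.113 for autophagy and lysosome and 0.133 for inflammatory signalling. The cell cycle list passed under median ratio scaling (median -0.63, adjusted p = 0.0272) and quantile normalization (-0.74, 0.0179), and the inflammatory list under quantile normalization (0.44, 0.0370). Adjusted p was 0.205 for acute phase, coagulation and complement, 0.220 for glycogen metabolism, 0.306 for lipoproteins and lipid transport, 0.447 for ketone body metabolism and for AMPK and mTOR signalling, and 0.494 for the urea cycle and purine breakdown. In the last list ass1, argininosuccinate synthase, averaged 37.0 ± 11.7 TPM in feeding and 14.7 ± 11.0 TPM in fasting fish and passed over the list alone (list-adjusted p = 0.0310). The remaining lists were the circadian clock (0.674), bile acids (0.907), the insulin, IGF and growth hormone axis (0.907), xenobiotic metabolism (0.929) and gluconeogenesis (0.971). The gluconeogenic phosphatase gene G6PC averaged 38.1 ± 32.1 and 95.4 ± 85.7 TPM and did not pass (adjusted p = 0.890 over all genes). For the bile acid, insulin and clock lists the median (-0.20, -0.15 and -0.12) and mean (-0.08, -0.10 and -0.05) were negative while the test against other genes pointed upwards.

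Among markers of other cell types, 7 of 12 lists had at least 3 tested members. The intestine list fell with a median of -1.97 over 3 members, FABP2, mogat2-a and ANPEP (adjusted p = 2.71e-05, and adjusted p = 0.00621 with an estimated correlation). Its estimated correlation was -0.0872, below the preset 0.01. FABP2 and mogat2-a passed over the list alone, mogat2-a (list-adjusted p = 0.000485), and ANPEP, an aminopeptidase of the intestinal brush border, averaged 5.42 ± 4.61 and 3.76 ± 1.80 TPM and did not pass (list-adjusted p = 0.654). Of these, mogat2-a also belonged to the triglyceride list and is described as 2-acylglycerol O-acyltransferase 1-like, so its place among intestine markers rests on the symbol, and FABP2 was the 1 member that passed over all genes. The other lists did not pass, with adjusted p = 0.941 for hepatocytes, bile duct epithelium and stellate cells, 0.242 for erythrocytes and endothelium, and 0.679 for macrophages and granulocytes. In the macrophage list LYZ, a lysozyme, averaged 9.72 ± 15.0 TPM in feeding and 26.3 ± 13.8 TPM in fasting fish and passed over the list alone (list-adjusted p = 0.0216), and the list's median (-0.29) and mean (0.12) differed in sign. The bile duct list had a median of -0.04 and a mean of -0.12 with a test pointing upwards. Lists for pancreas, lymphocytes, muscle, kidney and gonad had too few members.

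The counts of genes came from limma's moderated test on log2(TPM + 1), which found 156 genes higher and 1161 lower at an unadjusted p under 0.05. This balance moved with the scale and the libraries: 766 higher and 1005 lower under median ratio scaling, 670 and 1091 under quantile normalization, 644 and 702 with the 10 most abundant genes set aside, and 1179 and 506 without fasting 1 and 2. The median log2 fold change over all tested genes was -0.13, against 0.05 after median ratio scaling and 0.02 after quantile normalization. It was 0.23 without fasting 1 and 2, so list medians in that setting stand against a higher baseline. Under both scalings 0 genes passed in either direction, although all 25 genes kept a negative fold change, with a median of -2.30 and -2.34 against -2.64. The medians of the 15 lists kept their sign and their call under both. An exact rank-sum test, whose smallest possible p is 0.00216 with 6 libraries per group, could hardly pass over 21806 genes and gave 0. Without 1 library, 0 to 6 genes were higher and 6 to 59 lower. The lower count was 14 without feeding 1, 59 without feeding 4, 6 without feeding 5, 54 without feeding 6, 57 without fasting 1, 13 without fasting 2, 58 without fasting 3, 7 without fasting 4 and 14 without fasting 5, and the higher count 6 without feeding 4, 1 without feeding 3 or 6 and 2 without fasting 1. By alternatives chosen after the data were seen, without fasting 1 and 2, 8 genes were higher and 42 lower, 19 of them among the 25, and with the log2 vitellogenin total as a covariate 0 genes, 8 pathway lists and 0 cell type lists passed. The calls that ended there were those of the egg protein, fatty acid synthesis, triglyceride, cholesterol, pentose phosphate, interferon, thyroid and intestine lists. With the covariate the 25 genes had a median log2 fold change of -1.87 and the intestine list of -1.85, against -0.79 over all tested genes.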

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

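In each group of 6 libraries, the library at either end was singled out when its gap to its nearest neighbour, divided by the range of the group, was over Dixon's 95% critical value for 6 values. Among 202 groups of values 11 passed, where chance gives about 1 in 20 (10.1), so a single passing value says little. Of the tests below, the 1 of whether nematode matches are wrong matches of fish genes was chosen after the result was seen.

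Summed values that passed came from genes matched to other organisms. Genes with a nematode match were left out of the lists, but 514 of them were among the 21806 tested genes, where 0 were called. In fasting 1, genes with a nematode match held 20544 TPM against 4.12 to 113 in the other fasting libraries (gap 0.995 of the range). In fasting 5, genes with a plant source in their Swiss-Prot match held 7554 TPM against 1027 to 2911 (0.711), and genes with a match to the bat genus *Rhinolophus* held 3100 TPM against 56.5 to 191 (0.956). Of the 546 genes above 0 in fasting 5 alone, 223 had such a plant match, 138 a *Rhinolophus* match and 88 a match to the carp genus *Cyprinus*. No explanation was tested for the values of fasting 5.

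The nematode matches were weighed further. Wrong matches of fish genes would appear in many libraries, but 87.2% of the 1128 genes were above 0 in fasting 1 alone, which argues against that. RNA of a nematode in or on the liver sample needs its abundant genes there, and 40 genes described as ribosomal proteins with a nematode match were above 0 in that library alone, with 583 TPM in all. The tables therefore fit nematode RNA in fasting 1, most often matched to *Toxocara* (613 genes) and *Ascaris* (268), while its way into the sample stays open and its bearing on feeding cannot be tested in 1 library. When genes of other organisms were set aside, an alternative chosen after the data were seen, 23 genes were lower in fasting.

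The other 8 values were single genes or list means, as log2(TPM + 1). Fasting 6 was high for the cholesterol list, with a mean of 4.58 against 0.92 to 1.62 in the other fasting libraries (gap 0.809 of the range), and for its members Acat2 (4.37 against 0.36 to 1.62, 0.686) and Dhcr24 (3.51 against 0.31 to 1.23, 0.714). These 3 share genes and are 1 event rather than 3. Fasting 6 was also low for DGAT2 (4.89 against 5.26 to 5.47, 0.638), a narrow range. Feeding 1 was high for the endoplasmic reticulum list (6.30 against 3.74 to 4.44 in the other feeding libraries, 0.725) and for its member PDIA4 (9.32 against 3.69 to 5.67, 0.650). Feeding 4 was low for OAT (2.36 against 3.94 to 4.61, 0.705), and fasting 2 was low for ssr1 (3.56 against 6.01 to 6.92, 0.729). No explanation was tested for these.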

How the results depend on the processing

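The alternatives with fasting 1 and 2 left out, the 10 most abundant genes set aside, genes of other organisms set aside and the vitellogenin total as a covariate were chosen after the data were seen, as were, for lists, the scalings, the stricter filter, the pseudocount of 0.01, annotated genes alone and ignoring the organism of the match. Against 25 genes lower and 0 higher in fasting, median ratio scaling and quantile normalization gave 0 lower and 0 higher (at an unadjusted p under 0.05, 1005 and 1091 lower and 766 and 670 higher), with a lowest adjusted p of 0.146 and 0.110. The median log2 fold change of the 25 was then -2.30 and -2.34 against -2.64, so the folds stayed nearly as large. The exact rank-sum test also gave 0 and 0 (995 lower and 99 higher unadjusted), but its smallest possible p here, 0.00216, leaves little room to pass over 21806 genes, so it says nothing about stability. Fewer genes were lower with a mean of at least 5 TPM (13), a pseudocount of 0.1 (11) or 0.01 (8), the 10 most abundant genes set aside (2) or the covariate (0, with 4772 lower and 141 higher unadjusted). More passed without robust moderation (1 higher, 45 lower), with the library number as a block (6 higher, 78 lower) and without fasting 1 and 2 (8 higher, 42 lower), the last joined to median ratio scaling giving 0 higher and 13 lower, 10 of them among the 25. The library number gave no visible pairing, as same-number correlations ran from -0.120 to 0.129 and only 4 of 12 libraries matched their own number best. Without a filter 29 genes were lower, with a minimum fold change of 1 on the log2 scale 25, and with annotated genes alone 17. All 25 kept a negative fold change in each of these settings in which they were tested.

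Without 1 library, 0 to 6 genes were higher and 6 to 59 lower: 14 lower without feeding 1, 59 without feeding 4, 6 without feeding 5, 54 without feeding 6, 57 without fasting 1, 13 without fasting 2, 58 without fasting 3, 7 without fasting 4 and 14 without fasting 5. Genes were higher without feeding 3 (1), feeding 4 (6), feeding 6 (1) and fasting 1 (2). The 15 pathway lists became 1 with an estimated correlation, 1 with fry and 8 with the covariate, and stayed between 13 and 19 in the other settings. The 1 cell type list became 0 with the covariate. With a mean of at least 5 TPM the count was also 0, but there ANPEP was filtered out. The intestine list then had fewer than 3 members and was not tested. With the covariate the thyroid and glucocorticoid list, higher otherwise, had a median of -0.61 (adjusted p = 0.801). Leaving out libraries lowers the number compared, and with annotated genes alone 8946 genes were tested against 21806. Setting the 10 most abundant genes aside, which rescaled the rest, raised the number tested to 23147. The cause of the changes was otherwise not tested. Among the values of named genes and lists, 2864 kept their side of the threshold, 60 newly passed, 105 no longer passed and 1 that had passed reversed. Values that passed in neither setting were counted as kept even where their direction changed. The bile acid median, for instance, was -0.20 with all libraries and 0.40 without fasting 1 and 2. TPM gives no depth, so no limit from counting can be set. Count-based size factors and count models were not run.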

Other observations

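Egg protein genes fell as a list in fasting *Coilia nasus* liver. Lists for metabolism and protein synthesis fell with the preset correlation alone, and none of them passed with an estimated correlation (adjusted p = 0.578 to 0.742). Of the tests below, those of composition, swapped labels and sex or maturity were chosen after the result was seen, as were the permutation tests over member means, the terms of the table's own annotation and the genes shown without fasting 1 and 2.

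The fall of the egg protein list was weighed against 3 explanations. A few genes taking most of fasting 1 and 2 would leave little change without these libraries and with median ratio scaling. The median was then -3.03, but leaving out these libraries had to deepen the fall, so the test does not decide on composition. Vitellogenin took 2.88% and 0.808% of TPM in fasting 1 and 2, against 0.00466%, 0.000163% and 0.00669% in fasting 4, 5 and 6. The shares show only that the deepest falls lay outside fasting 1 and 2. Swapped labels stay open: the lowest vitellogenin share of a feeding library was 1.20%, so none was near 0 as fasting 4, 5 and 6 were, but a swap that involves another fasting library, or whole groups, would leave no trace in this value. Sex or maturity stays open: 2 fasting libraries lay within the feeding range of vitellogenin share and 3 were near 0, as a mix of maturing females and other fish could give, but the labels name neither and the test decides nothing. Fasting itself, the difference the design names, also stays open and was not tested apart from these.

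The metabolic and ribosomal lists that fell (13 lists, 358 members, 337 of them negative, median -0.94) were weighed against composition and against gene length and abundance. In 1000 draws of annotated genes matched on length and mean TPM the medians ran from -0.46 to -0.23 with a median of -0.34. Genes of like length and abundance outside these lists therefore fell less. The size of the members' own fall is raised by the choice of lists that fell, so a gap to the draws was likely in advance. The draws therefore do not decide whether length and abundance gave the fall. Composition stays open: without fasting 1 and 2 and with median ratio scaling the members' median was -0.62, but the exact permutation p of their mean was 0.0762 over the 210 splits of the 10 libraries, where composition would have been excluded at under 0.05. The p was 0.0455 over the 924 splits of all libraries and 0.0152 with scaling alone, and each of the 3 may be too low because the members come from lists chosen for their fall under these labels. Sex or maturity, which the labels do not name, stays open as well for these lists and for the 25 genes, and was not tested. With the vitellogenin covariate 0 genes passed. The fatty acid synthesis, triglyceride, cholesterol, pentose phosphate and interferon calls ended, while 8 pathway lists passed. The vitellogenin share itself differed between the groups, so the covariate decides nothing here. Fasting itself also stays open and was not tested apart from these.

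Other splits of the 12 libraries into equal groups gave results as large often enough that chance cannot be excluded for the counts. Among 100 splits, the real 1 included, 5 gave at least 25 genes, and the highest other gave 431, with feeding 1, 3, 5 and 6 and fasting 1 and 2 on 1 side. A count so far above the real 1 points to a structure of the samples. The other splits with at least 25 genes (431, 325, 141 and 124) all had fasting 1 and 2 with feeding 1 and 3 on 1 side. Further splits with these libraries together gave as few as 0 genes, and the cause was not tested. In 80 splits 0 genes passed. For pathway lists with the preset correlation 14 splits gave at least the real 15 (highest other 22), and for cell type lists 39 gave at least the real 1 (highest other 2). The other splits called a median of 8 pathway lists with the preset correlation, and 3 of them called 0. A pass with that correlation is therefore common under arbitrary groupings. For pathway lists with an estimated correlation 3 splits gave at least the real 1 (highest other 1), under the bound of 5 set beforehand. With only 1 list called, and several counts tested without adjustment, chance is not excluded for it either.

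Across libraries, the first 2 principal components held 30.7% and 15.3% of the variance. Correlations between libraries ran from 0.732 to 0.841 within feeding, 0.510 to 0.810 within fasting and 0.586 to 0.873 between the groups. A 214-base gene without annotation held 0.445% to 35.3% of TPM. The uncharacterised gene TRINITY_DN45478_c1_g1 held 372, 564, 16806, 44225, 170011 and 103931 TPM in fasting 1 to 6 and 139 to 12703 TPM in the feeding libraries. The gene mid1ip1a, described as thyroid hormone-inducible hepatic protein, held 556 to 22740 TPM in feeding and 2340, 330, 750, 72.6, 18.4 and 64.9 TPM in fasting 1 to 6. Outside the 10 most abundant genes, mitochondrially encoded genes took 5.03% ± 2.27 in feeding and 3.92% ± 1.02 in fasting libraries (exact permutation p = 0.305). The other library measures gave exact permutation p = 0.504 for ribosomal-RNA-like genes, 0.232 for the 10 most abundant genes, 0.673 for the median TPM and 0.439 for the 214-base gene (adjusted 0.605, 0.463, 0.673 and 0.605).

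Of 216 pathway terms in the table's own annotation with at least 10 tested genes, 55 were lower and 0 higher with the preset correlation, and 0 passed with an estimated one (lowest adjusted p = 0.997). They included oxidative phosphorylation (138 genes, median -0.81) and propanoate metabolism (41 genes, -0.93). Without fasting 1 and 2 the 8 genes that were higher included C1QTNF9 (log2 2.18, adjusted p = 0.0441) and Sec14l2 (2.75, 0.0431).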
